A study of Zea mays with 10 samples.

How the data were processed

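Small RNA was sequenced from leaf and root of 14-day-old maize (Zea mays) seedlings. There were 10 libraries, with 1 library for each line and tissue. Leaf libraries came from 6 lines (B73, id1, id4, 9d9a, 714 and 714H) and root libraries from 4 of them (B73, id1, id4 and 9d9a). Groups were taken from the sample titles, which give leaf or root; the tissue label of the leaf libraries reads seedling. Per the labels' protocols, total RNA was extracted with PureLink reagent and treated with DNase, and a sequencing centre made the libraries with standard Illumina methods. Bowtie is named in the submitters' processing notes. Its version and settings, the genome build, the range of read lengths kept and the treatment of reads with several genomic matches are not given in the sources used here.

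The deposited files hold counts, namely whole-number read totals per consecutive 100 kb window of the 10 chromosomes, per the file headers and values. The authors made no further normalisation of these counts that the files show, since totals differed between libraries. Windows without reads were not listed, and were taken as 0. The position given for a window was read as its start. There were 20584 windows with reads in any library and 20525 with reads in every library. Because reads mapping to many places can be counted in several windows or left out, and because reads were matched to 1 reference genome, a window's count depends on how closely a line's sequence matches that reference. No annotation of that build was used here, so windows are given by chromosome and position and were not placed in genes, exons or introns.

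Totals ranged from 8472011 to 18396214 reads per library. The median window held 229 to 506 reads, which gives a relative counting error (SE) of 6.6% to 4.4%. Intervals on counts cover counting error only, since reads without molecular identifiers are not independent molecules. No libraries were duplicates. The closest pair, the 714 and 714H leaf libraries, had a chi-square of 5.48 per degree of freedom over windows, where sampling noise alone gives about 1.

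The designs, tests, alternatives and the rule for named windows were fixed before the data were examined. Window counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the default filter on low counts, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at a threshold of 0.05. The SE of a log2 change was derived from the F statistic of the fit. Where reads are few it can be smaller than counting error alone. Leaf was compared with root over the 8 libraries of the 4 lines sequenced in both tissues, so that lines served as the replicates of a tissue (6 residual degrees of freedom). Each of id1, id4 and 9d9a was compared with B73 in the same 8 libraries with tissue as a covariate (3 residual degrees of freedom), which tests the part of a line's effect shared by leaf and root. The effect of the 714 allele was fitted as a slope per copy over the 6 leaf libraries, with 2 copies in 714, 1 in 714H and 0 in the others (4 residual degrees of freedom). Nothing in the labels says that libraries came from several plants, so p-values measure the spread between these libraries. The common biological coefficient of variation was 0.183 for leaf and root, 0.0841 for the line models and 0.161 for the slope.

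Regional values are medians over windows with a mean of at least 5 counts in the leaf libraries, on the scale log2(CPM + 1), where CPM are counts scaled to the TMM-adjusted library size. The intervals beside them are 95% intervals of the median from the binomial distribution of ranks. They describe the scatter of windows within a library pair, not the scatter of plants. The flanks are the 15 Mb on either side of 48 Mb on chromosome 1, an approximate position of p1 that was set before the data were examined. For the flank test, each library's median deviation from the 6-library mean, less that of all windows outside the flanks, was correlated with the copies of the 714 allele, with an exact two-sided permutation test over 30 placements. Lists of windows were compared with 10000 random lists of the same size from outside the flanks, matched on mean level. The random windows were scattered over the genome and drawn with no condition on root level. A rank among them does not show how often a run of neighbouring windows would lie as far out. The regional scan used 5 Mb blocks with at least 20 windows. Ratios of single libraries carry exact (Clopper-Pearson) intervals of the conditional binomial share.

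The named windows were, for leaf against root, the 10 farthest in each direction among windows past the threshold that moved the same way in all 4 lines. For each line they were the 5 that rose and the 5 that fell most among those past the threshold with the same direction in both tissues. For the 714 slope they were the 10 steepest in each direction among those past the threshold with 714H between B73 and 714, and for the scan the 3 blocks farthest from 0 in each library.

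Lines paired the tissues. The deviation of a line's leaf library from the leaf mean correlated across windows with that of its root library at 0.642 (B73), 0.797 (id1), 0.562 (id4) and 0.665 (9d9a), against at most 0.004 between different lines. The fit with line as a block was an alternative.

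The fits were tested on simulated data in which 200 windows were changed. For leaf against root (20215 windows), 19.4% of windows changed 1.5-fold, 79.1% of those changed 2-fold and 100% of those changed 4-fold were recovered. For id1 against B73 (20386 windows) the shares were 64.2%, 77.6% and 98.5%, and for the 714 slope per copy (20345 windows) 61.2%, 95.5% and 98.5%. A simulated 2-fold rise of the high flank in 714 came back as a median log2 of 0.95 over 149 windows. Those reads had counting noise only and no other difference between lines. The simulation thus does not show that such a rise would be seen in the real flank.

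Alternatives were the DESeq2 1.42.0 Wald test, library totals without TMM, RLE size factors, other filters, leaving out lines or libraries, other pseudocounts, flank lengths, scan blocks and references. Thinning the reads of the B73 leaf library, the windows close to B73 in root, the comparisons of 714 with id1 and id4, the midpoint comparison, the chromosome centres and the runs of lower blocks were added after seeing the data. The planned results on miRNA families, on read length classes and on listed genes were not computed, because the windows carry no sequences, lengths or gene names. The remaining analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.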

Results

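The series concerns the dosage effect of copy number alterations on small RNA in maize. Reads were counted in 100 kb windows over the 10 chromosomes in B73, the inbred line behind the maize reference genome, and in lines named for alleles of p1. The p1 gene on chromosome 1 encodes a Myb-type regulator of red pigment in floral tissues, and the letters of an allele name give the colour of pericarp and cob. The lines were id1 (P1-wwid1), id4 (P1-wwid4), 9d9a (P1-vv9d9a), 714 (P1-ww714) and 714H, which carries the 714 allele over B73. Each line had 1 library per tissue. B73, id1, id4 and 9d9a were sequenced in leaf and root, and 714 and 714H in leaf. The B73 leaf library held 18396214 reads, the other leaf libraries 8472011 to 10017497, and the root libraries 10921854 to 12160298. The coordinates are those of the deposited windows, whose genome build is not given in the sources used here.

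Leaf and root differed at windows on every chromosome. A window at 82.4 to 82.5 Mb of chromosome 10 held 507 ± 24.9 CPM in leaf and 3.20 ± 1.92 CPM in root (SD, n = 4 lines), a log2 difference of 7.31 ± 0.41 (SE). A window at 183.5 Mb of chromosome 5 held 6962 ± 585 CPM in leaf and 365 ± 469 CPM in root, and the id4 root library alone had 1064 CPM there. On chromosome 4 the window at 121.9 Mb held 79.7 ± 9.01 CPM in leaf and 8.19 ± 1.85 in root, and on chromosome 5 the window at 73 Mb held 194 ± 16.8 in leaf and 40.9 ± 3.97 in root. In the other direction, a window at 288.9 Mb of chromosome 1 held 200 ± 42.2 CPM in root and 26.4 ± 9.71 in leaf, and one at 8.0 Mb of chromosome 10 held 156 ± 27.6 in root and 31.4 ± 1.62 in leaf.

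Of 20215 windows tested, 5111 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2293 higher in leaf and 2818 higher in root. Which direction held more windows depended on the scaling, with 2471 higher in leaf and 2442 in root when library totals replaced TMM. In 5060 of them all 4 lines had the same direction. The differences were mostly small, with a median absolute log2 change of 0.47 among the windows called. Over 2-fold differences were found for 147 windows higher in leaf and 173 higher in root. The share of windows called ran from 19.5% on chromosome 1 to 29.1% on chromosome 9. The adjusted p was 7.52e-05 at the chromosome 10 window at 82.4 Mb, 2.44e-06 at 121.9 Mb of chromosome 4, 0.021 at 183.5 Mb of chromosome 5, 0.00111 at 288.9 Mb of chromosome 1 and 3.08e-06 at 8.0 Mb of chromosome 10.

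The other named windows higher in leaf lay on chromosome 1 (127.7 Mb, log2 3.21 ± 0.30 SE), chromosome 7 (150.3 Mb, 3.20 ± 0.57), chromosome 5 (20.5 Mb, 2.85 ± 0.21), chromosome 9 (63 Mb, 2.72 ± 0.14), chromosome 7 (164.3 Mb, 2.35 ± 0.22) and chromosome 2 (131.9 Mb, 2.28 ± 0.26). Those higher in root lay on chromosome 9 (131.2 Mb, log2 of leaf over root -3.07 ± 0.66), chromosome 1 (214.5 Mb, -2.75 ± 0.36), chromosome 10 (90.1 Mb, -2.72 ± 0.22, and 125.7 Mb, -2.36 ± 0.15), chromosome 3 (7.7 Mb, -2.36 ± 0.44, and 89.9 Mb, -2.17 ± 0.17), chromosome 5 (115.6 Mb, -2.30 ± 0.14) and chromosome 4 (144.1 Mb, -2.22 ± 0.13). The call at 131.2 Mb of chromosome 9 was lost with line as a block (log2 -2.75) and without B73 (-3.27), id4 (-2.76) or 9d9a (-2.57). Without B73, id1 or 9d9a the calls at 183.5 Mb of chromosome 5 (3.92 to 4.05) and 7.7 Mb of chromosome 3 (-2.38 to -2.16) were lost, and without B73 also that at 150.3 Mb of chromosome 7 (2.94). The number of windows called depended on the lines used, with 2994 without B73, 3346 without id1 and 3373 without 9d9a.

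**Figure D1:**
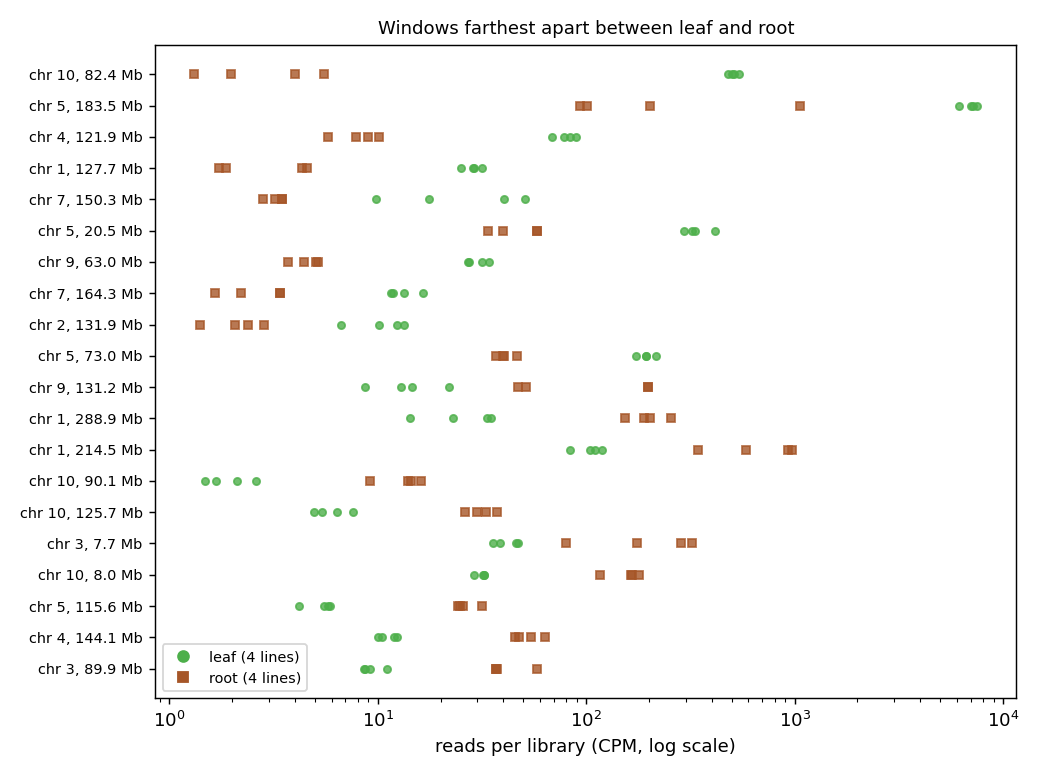
Reads per library in CPM (horizontal log axis) at the 20 named windows of the leaf and root comparison, with 1 point per library, circles for leaf and squares for root of B73, id1, id4 and 9d9a. The leaf and root points of a window do not overlap, as at 82.4 Mb of chromosome 10 with a mean of 507 CPM in leaf and 3.20 CPM in root.

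The comparison of each line with B73 asks where in the genome the p1-allele lines differed in small RNA from B73 in leaf and root alike. The window at 48.1 to 48.2 Mb of chromosome 1, next to the position taken for p1, stood out in id1 and id4. B73 had 24.4 CPM there in leaf and 20.4 in root. In id1 the level was 1271 CPM in leaf and 502 in root, and in id4 it was 962 in leaf and 482 in root. The 9d9a libraries had 33.9 CPM in leaf and 25.8 in root. The log2 change was 5.19 ± 0.32 (SE) in id1 and 4.94 ± 0.32 in id4, with adjusted p of 0.000334 and 0.000563 in edgeR, n = 2 libraries per line.

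Outside that window, long blocks of the genome lay lower than B73, at the same places in leaf and root. In id1 the blocks were on chromosome 1 at 30 to 45, 50 to 65, 70 to 90 and 220 to 230 Mb, on chromosome 2 from 225 Mb to its end at 237.1 Mb and on chromosome 10 at 140 to 145 Mb. The lowest 5 Mb median log2 ratio to B73 was -1.74 in leaf and -1.93 in root, both within 50 to 65 Mb. In id4 the leaf blocks were on chromosome 1 at 20 to 45 and 50 to 85 Mb and on chromosome 2 at 10 to 25 and 30 to 35 Mb, with a lowest median of -1.50 in leaf and -2.01 in root. In 9d9a they were on chromosome 1 at 25 to 45 and 225 to 245 Mb, on chromosome 7 at 10 to 25, 90 to 95 and 100 to 105 Mb and on chromosome 2 at 5 to 10 Mb, with a lowest median of -1.71 in leaf and -1.57 in root. In root, 50 to 55 Mb of chromosome 1 in 9d9a also met the criterion, and the blocks at 30 Mb of chromosome 2 in id4 and 10 Mb of chromosome 7 in 9d9a ran 5 Mb farther. A block here is a run of 5 Mb intervals with a median log2 ratio of -0.3 or less, a rule chosen after seeing the data. These blocks summed to 77.1 Mb in id1, 80 Mb in id4 and 70 Mb in 9d9a in leaf, and to 77.1, 85 and 80 Mb in root.

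Window by window, 395 windows rose and 729 fell in id1, 290 rose and 630 fell in id4, and 313 rose and 627 fell in 9d9a, of 20386 tested (edgeR, adjusted p under 0.05). DESeq2 called fewer that rose, 248 in id1, 172 in id4 and 197 in 9d9a. Of the windows that fell, 447 in id1, 344 in id4 and 298 in 9d9a were on chromosome 1. A further 100 in id1 and 171 in id4 were on chromosome 2, and 220 in 9d9a were on chromosome 7. With 1 library per line and tissue the comparison has 3 residual degrees of freedom, and effects present in a single tissue were not tested.

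Several windows within the blocks were nearly empty in a line. At 53.5 Mb of chromosome 1, id1 had 0.20 CPM in leaf and 0.36 in root against 65.8 and 50.1 in B73 (log2 -7.62 ± 0.28, adjusted p 3.01e-11), and id4 had 2.08 and 3.31 CPM (log2 -4.39 ± 0.19, adjusted p 2.19e-09). The id1 values rest on 2 reads in leaf and 4 in root. Counting error alone is larger than the SE of 0.28 there, so the size of the change is uncertain. At 227.9 Mb of chromosome 2, id1 had 0.20 CPM in leaf (2 reads) and 0.09 in root (1 read) against 26.0 and 33.1 in B73. At 79.7 Mb of chromosome 1, id1 had 4.37 and 3.64 CPM against 365 and 454 in B73. The windows at 79.9 and 63.8 Mb of chromosome 1 completed the 5 that fell most in id1, with log2 changes of -6.87 ± 0.31 and -6.53 ± 0.24. In id1 leaf and root the window at 79.9 Mb held 2 and 2 reads, and that at 63.8 Mb held 10 and 6. Counting error alone is larger than the SE at both. In id4 the other 4 of the 5 that fell most were at 50.6, 52.7, 52.9 and 54.4 Mb of chromosome 1, with log2 changes from -5.05 to -4.24. The change of -5.05, at 52.9 Mb, rests on 5 reads in id4 leaf and 2 in root. At 54.4 Mb there were 7 and 16, so the sizes of both changes are uncertain. In 9d9a the 5 were at 34.1, 36.2, 36.3, 42.7 and 44.2 Mb of chromosome 1, led by 42.7 Mb with 0.94 CPM in leaf against 75.7 in B73 (log2 -6.42 ± 0.20). There 9d9a had 8 reads in leaf and 7 in root, and counting error alone is again larger than the SE. In 9d9a leaf and root the window at 44.2 Mb held 3 and 1 reads, and that at 36.2 Mb 5 and 11.

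Windows that rose most in id1 included 233.8 Mb of chromosome 2, inside a lower block, with 709 CPM in leaf and 744 in root against 6.51 and 5.51 in B73 (log2 6.92 ± 0.21, adjusted p 6.1e-09). The others were at 179.4 and 75.2 Mb of chromosome 1 and 176.7 Mb of chromosome 7, with log2 changes of 4.91 ± 0.17, 3.54 ± 0.15 and 4.53 ± 0.45. In id4 they were at 137.1 Mb of chromosome 9 (419 CPM in leaf against 42.9 in B73), 133.3 and 86.0 Mb of chromosome 1 and 67.4 Mb of chromosome 8. The window at 67.4 Mb of chromosome 8 also led the list of 9d9a. It held 7.16 CPM in B73 leaf, 55.5 in id4, 60.1 in 9d9a, 62.9 in id1, 69.1 in 714 and 35.8 in 714H, so that the B73 library was the low one. The other windows that rose most in 9d9a were at 43.0, 61.1 and 91.1 Mb of chromosome 7 and 133.3 Mb of chromosome 1, with log2 changes between 2.39 and 2.47, and without id1 the call at 91.1 Mb was lost (2.38).

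**Figure D2:**
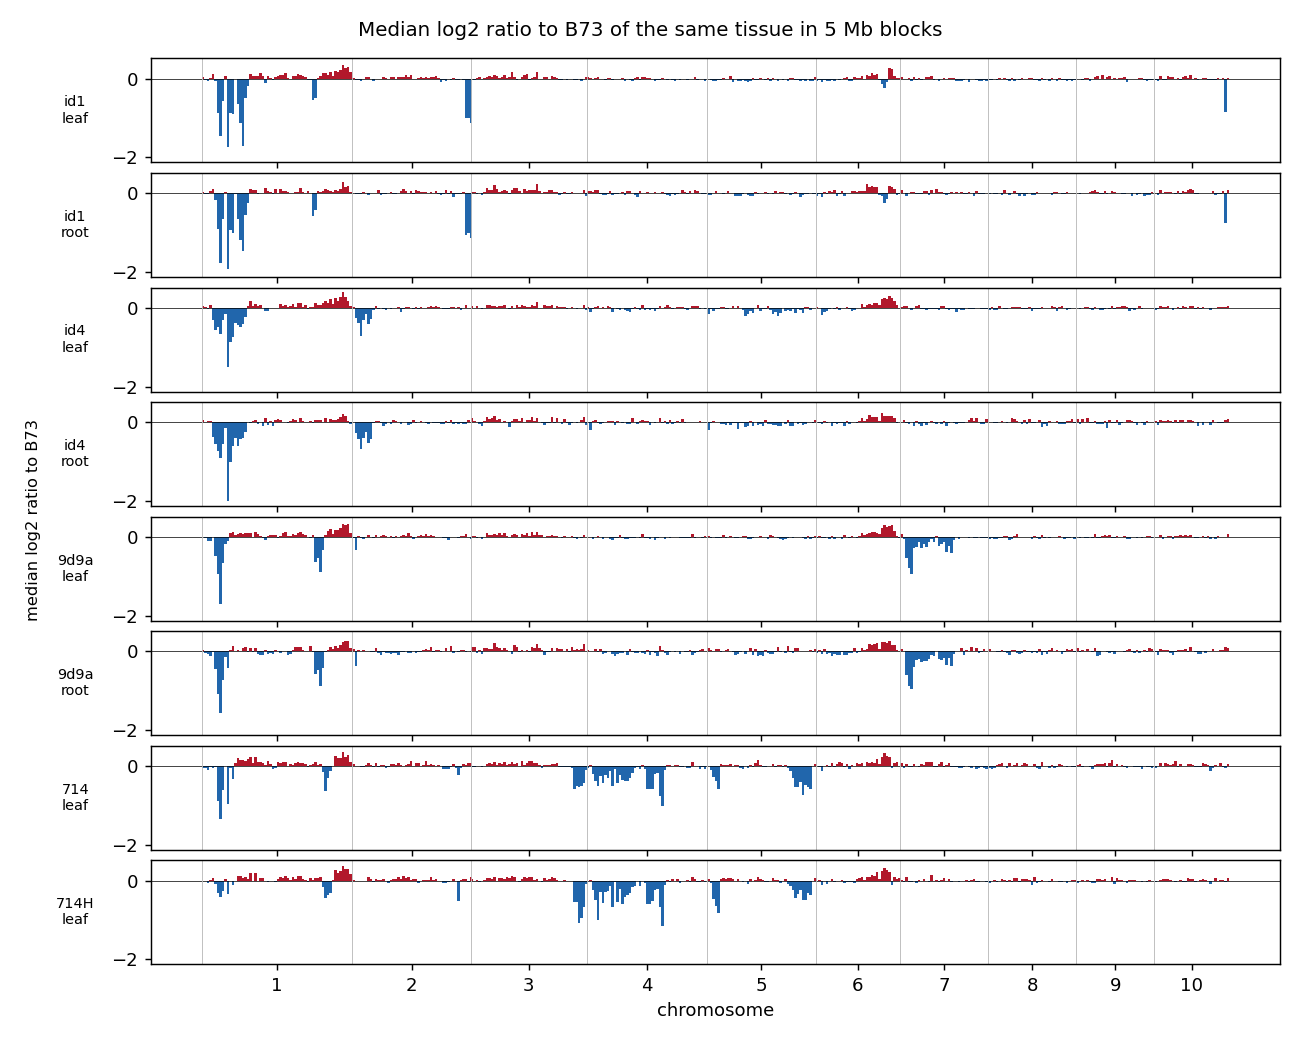
Median log2 ratio of window counts to B73 of the same tissue (vertical axis) in 5 Mb blocks along chromosomes 1 to 10 (horizontal axis), with 1 row per library, blue below 0 and red above 0. Lower blocks of id1, id4 and 9d9a recur in leaf and root, and those of 714 and 714H lie mainly on chromosomes 1, 3, 4 and 5.

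The comparison by copies of the 714 allele asks which windows changed with the dose of that allele in leaf. Windows that fell were concentrated on chromosomes 4 and 5, away from p1. Only the 714 and 714H libraries carried the allele, so its dose cannot be told apart from the background of those stocks. At 142.5 Mb of chromosome 4, B73 had 26.9 CPM, 714H 5.14 and 714 3.24, while id1, id4 and 9d9a had 26.5 to 27.7. At 147.5 Mb of chromosome 4 the levels were 88.4 CPM in B73, 29.2 in 714H and 19.2 in 714. Of the windows that rose, that at 280.4 Mb of chromosome 1 had 19.8 CPM in B73, 68.0 in 714H and 79.4 in 714, and that at 109.1 Mb of chromosome 4 had 12.6, 28.4 and 45.7. The slopes per copy were -1.69 ± 0.17 (SE), -1.19 ± 0.11, 1.07 ± 0.15 and 0.90 ± 0.14 in log2, with adjusted p of 0.00775, 0.00746, 0.0281 and 0.03 in edgeR. On the CPM scale, where an additive effect puts 714H at 0.5 of the distance from B73 to 714, 714H lay at 0.33 to 0.95 (median 0.80) in the 10 that rose and at 0.73 to 0.94 (median 0.89) in the 10 that fell. The rule for these windows kept 714H within that distance, and a fall linear in log2 already puts it beyond 0.5. No error was computed for these shares, and some rest on few reads. At 105.5 Mb of chromosome 4 there were 46 in B73, 10 in 714H and 6 in 714.

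Of 20345 windows tested, 130 rose and 348 fell per copy. Of those that fell, 137 were on chromosome 4, 136 on chromosome 5, 34 on chromosome 1 and 31 on chromosome 3. In the high flank of p1, 48 to 63 Mb of chromosome 1, 14 of 148 windows changed, all of them rising and all beyond 51 Mb. In the low flank, 33 to 48 Mb, 1 of 148 windows changed, and it fell. The remaining named windows that fell were at 143.2, 143.5, 147.4, 147.6, 150.6, 151.7 and 105.5 Mb of chromosome 4 and 192.7 Mb of chromosome 5, with slopes from -1.27 to -1.03. Those that rose were at 93.3, 124.6, 131.8 and 167.9 Mb of chromosome 4, 22.5 Mb of chromosome 6, 60.3 Mb of chromosome 3 and 91.9 and 138.9 Mb of chromosome 2, with slopes from 0.89 to 1.27. The total rests on single libraries. It was 94 without B73, 280 without id1, 176 without id4, 182 without 9d9a, 971 without 714 and 941 without 714H, and DESeq2 called 1132. Of the 20 named windows, 14 lost the threshold without B73, 10 without id1, 13 without id4, 14 without 9d9a, 3 without 714 and 17 with B73, 714H and 714 alone, while none changed sign. Of the windows given with adjusted p above, those at 142.5 and 147.5 Mb of chromosome 4 lost it with the 3 libraries alone, that at 280.4 Mb of chromosome 1 also without B73, id1, id4 or 9d9a, and that at 109.1 Mb of chromosome 4 without B73, 9d9a or 714.

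As single libraries, 714 and 714H have no replicate check against B73, and their ratios compare the libraries only. In the 10 named windows that fell, the 714 to B73 ratio lay between 0.12 and 0.26 and that of 714H between 0.19 and 0.46, and all exact 95% counting intervals lay below 1. In the 10 that rose, the 714 ratio lay between 2.85 and 4.47 and that of 714H between 1.61 and 3.50, with the intervals of 10 and 9 of them above 1. These windows were chosen by their slope over the same counts, so the side of 1 on which the ratios lay was set by the choice. At 48.1 Mb of chromosome 1 the ratio to B73 in leaf was 56.9 in 714 (95% interval 51.8 to 62.6) and 24.1 in 714H (21.9 to 26.6). There 714 had 1388 CPM and 714H 589.

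Along chromosome 1 the segment beside p1 was not uniform. From 48 to 51 Mb (30 windows) the median log2 ratio to B73 in leaf was 1.04 in 714 (95% interval 0.82 to 1.23), 0.52 in 714H (0.39 to 0.68), 0.99 in id1 (0.83 to 1.11), -0.01 in id4 (-0.16 to 0.10) and -0.04 in 9d9a (-0.22 to 0.05). In root it was 0.95 in id1, -0.02 in id4 and -0.01 in 9d9a. From 51 to 63 Mb (119 windows) the medians in leaf were -0.42 in 714, -0.13 in 714H, -1.32 in id1, -1.09 in id4 and 0.08 in 9d9a. In the same windows 714 lay above id1 by a median log2 of 0.88 (0.77 to 0.97), in 109 of 119 windows, and above id4 by 0.76 (0.61 to 0.88). From 63 to 66 Mb the median of 714 over id1 was 0.02 (-0.08 to 0.11), and in the low flank it was 0.08 (0.00 to 0.15).

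**Figure D3:**
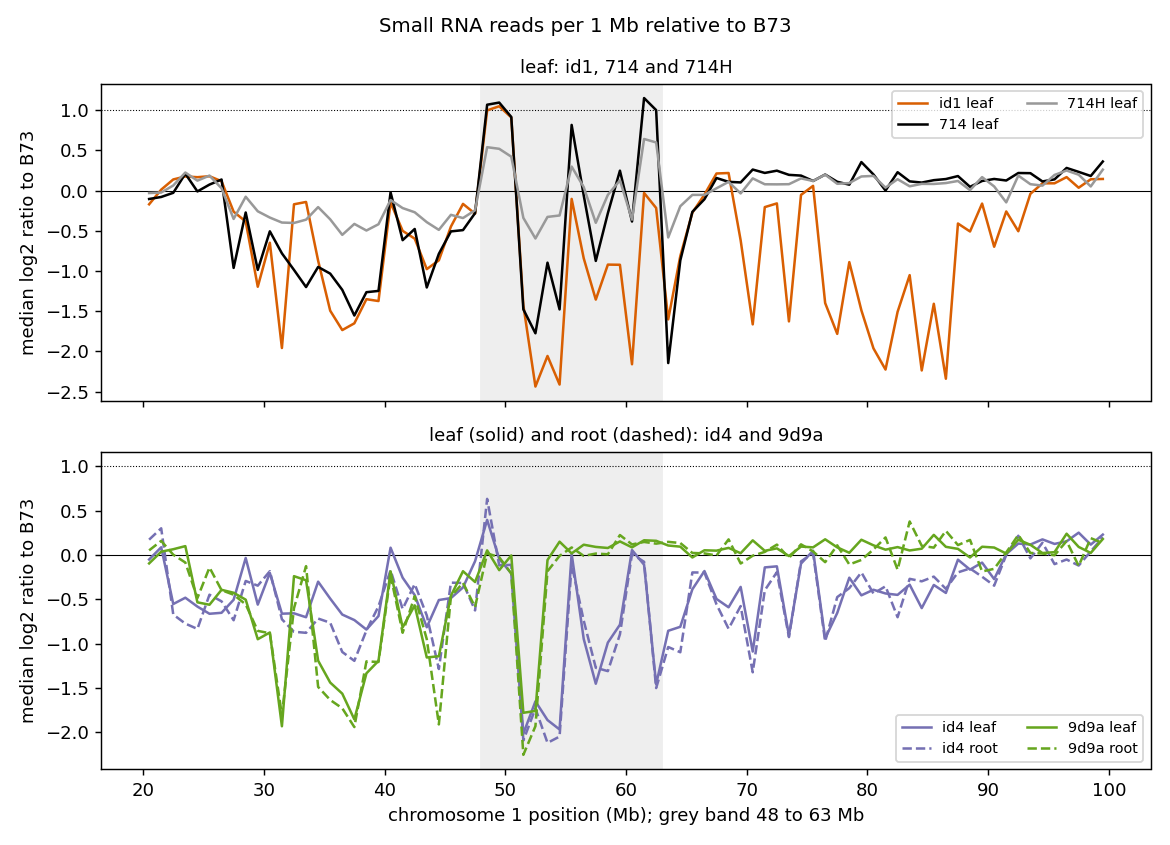
Median log2 ratio to B73 of the same tissue per 1 Mb (vertical axis) along 20 to 100 Mb of chromosome 1 (horizontal axis), for id1, 714 and 714H leaf (top) and for id4 and 9d9a leaf and root (bottom), with 48 to 63 Mb shaded and a dotted line at a log2 ratio of 1. From 48 to 51 Mb, 714 and id1 lie near 1 and 714H near 0.52, and from 52 to 63 Mb 714 runs above id1.

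Over the whole 15 Mb high flank the median log2 ratio to B73 was 0.01 in 714 and -0.01 in 714H, at percentiles 73.7 and 52.7 among the random lists. In the low flank it was -0.99 in 714 and -0.34 in 714H, below all 10000 random lists, and it was -0.98 in id1, -0.55 in id4 and -0.92 in 9d9a as well. Against the mean of the 4 leaf libraries without the allele, the medians in the high flank were 0.50 in 714 and 0.48 in 714H, and in the low flank -0.24 and 0.32.

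The flank test set the library medians against the copies of the 714 allele. In the low flank the values were 0.65 in B73, -0.33 in id1, 0.09 in id4, -0.33 in 9d9a, 0.30 in 714H and -0.31 in 714, and Pearson's r was -0.21 (exact permutation p = 0.7, adjusted 0.7 over the 2 flanks; Spearman's rho 0.14, exact permutation p = 0.8). In the high flank they were 0.35, -0.54, -0.60, -0.03, 0.35 and 0.30 in the same order, and r was 0.56 (exact permutation p = 0.3, adjusted 0.6; rho 0.37, exact permutation p = 0.467). The smallest p that the 30 placements allow is 0.033, or 0.067 after adjustment if a single flank reaches it, so a trend in 1 flank alone could not pass the threshold. Without 714 and 714H no library carries the allele, so r rests on those libraries, and in the low flank its sign changed to 0.14 without B73 and 0.31 without 714.

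**Figure D4:**
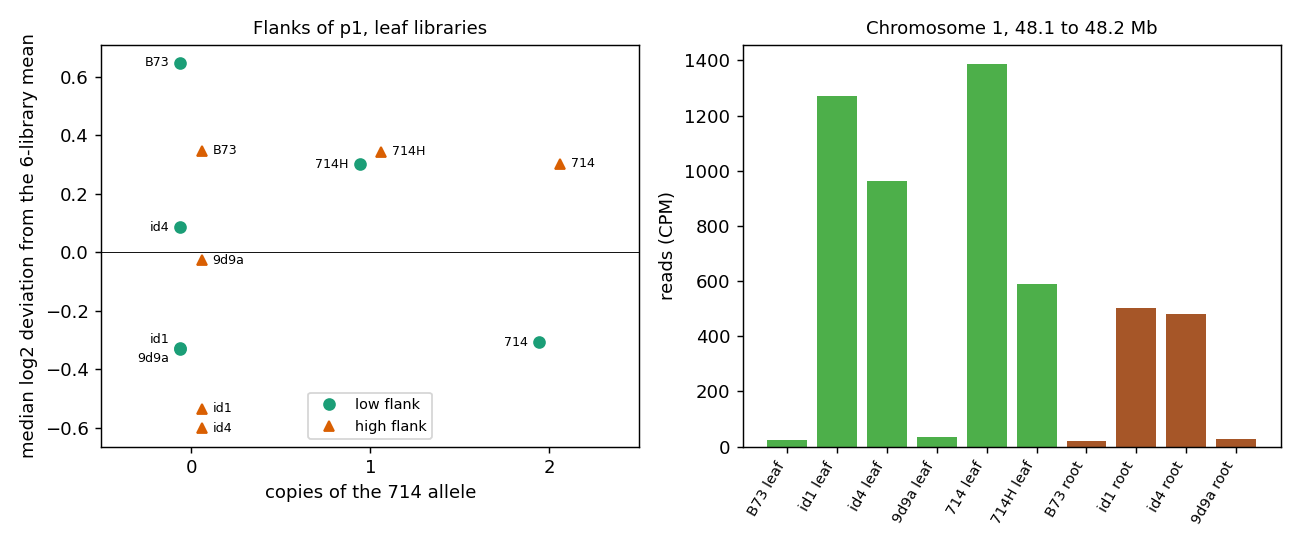
Left, median log2 deviation of each leaf library from the 6-library mean in the low flank (circles) and high flank (triangles) of p1 against the copies of the 714 allele. Right, reads in CPM at 48.1 to 48.2 Mb of chromosome 1 in each library, leaf green and root brown, from 20.4 CPM in B73 root to 1388 CPM in 714 leaf.

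The regional scan, in which each library is set against the mean of the others of its tissue, found the following blocks farthest from 0. B73 lay highest at 50 to 55 Mb (1.34 in leaf, 1.46 in root), 35 to 40 Mb (1.07 and 1.34) and 30 to 35 Mb (0.68 and 0.90) of chromosome 1. The farthest block of id1 was at 80 to 85 Mb of chromosome 1 (-1.68 in leaf, -1.33 in root), followed in leaf by the last block of chromosome 2, from 235 Mb (-1.19), and 75 to 80 Mb of chromosome 1 (-1.14). In id4 it was 50 to 55 Mb of chromosome 1 (-0.91 and -0.77), with 55 to 60 Mb of chromosome 1 and 15 to 20 Mb of chromosome 2 next in both tissues. In 9d9a it was 235 to 240 Mb of chromosome 1 (-1.01 and -1.09), and 20 to 25 Mb of chromosome 7 was at -0.92 and -0.93, with 35 to 40 Mb of chromosome 1 at -0.94 in leaf. The 714 library lay lowest at 150 to 155 Mb of chromosome 4 (-0.81), where 714H was at -0.87, and 714H lay lowest at 215 to 220 Mb of chromosome 3 (-0.91). In all, counting 4 blocks that end with their chromosome as 5 Mb, 180 Mb of the 2060 Mb scanned lay below -0.2 in 714, 170 Mb in 714H, 100 Mb in 9d9a, 95 Mb in id1, 70 Mb in id4 and 30 Mb in B73 leaf, while 45, 75, 120, 115, 125 and 155 Mb lay above 0.2 in the same order. In root, 15 Mb lay below -0.2 and 105 Mb above 0.2 in B73, 95 and 35 Mb in id1, 60 and 55 Mb in id4 and 90 and 75 Mb in 9d9a.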

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

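The tests for single outlying libraries used a fixed criterion, and the chance split was planned. Among 54 groups of 4 or 6 libraries tested, 6 had a library whose gap to the nearest other exceeded Dixon's 95% critical value, as a share of the range of the group. In 100000 simulated groups of normal values, 5.1% did so by chance with 4 libraries and 5.2% with 6.

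The B73 leaf library had 18396214 reads, against 8472011 to 10017497 in the other 5 leaf libraries. It also had the lowest share of reads in the central part of the chromosomes among leaf libraries, 34.3% against 35.0% to 35.3%. Among root libraries, id1 had the highest such share, 34.7% against 33.9% in the others. At 183.5 Mb of chromosome 5, one of the windows farthest apart between the tissues, the id4 root library had 1064 CPM and the other root libraries 93.6 to 201 CPM. At 8.0 Mb of chromosome 10, id1 leaf had 29.0 CPM and the other lines 31.9 to 32.4. At 89.9 Mb of chromosome 3, 9d9a root had 58.1 CPM and the others 37.0 to 37.4.

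When the reads of the B73 leaf library were thinned to the median of the other leaf libraries, a step added after seeing the data, 4999 windows differed between leaf and root and 4886 of them were among the 5111. The counts for id1, id4, 9d9a and the 714 slope were then 1080, 874, 915 and 463.

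Of the 35 splits of the 8 libraries into 4 against 4, 1 gave as many windows as leaf against root (5111), the real one. Lines pair the tissues, so the 27 splits that keep both tissues of a line together also part the lines, and the 8 that part the tissues of all 4 lines are too few for a share under 0.05. The highest of the other splits called 76, and it set B73 and 9d9a against id1 and id4, a split by line. Among the 8 splits that part the leaf and root libraries of all 4 lines, those other than the real one called 0 windows in edgeR, with 91 to 1386 windows at an unadjusted p under 0.05, and 0 in DESeq2.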

How the results depend on the processing

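The thinned reads, the windows close to B73 in root and the ratios of 714 to id1 and id4 were alternatives chosen after seeing the data. From 51 to 63 Mb of chromosome 1, the median log2 of 714 over id1 (0.881) depended on the pseudocount. It was 0.984 with 0.1 CPM and 0.669 with 5 CPM. That of 714 over id4 (0.76) was 0.876 and 0.592. Without 1 line in turn, the leaf and root comparison gave 2994 to 4119 windows against 5111. With line as a replicate block it gave 7637, of which 5099 were among the 5111, and it changed the call of 1 named window, at 131.2 Mb of chromosome 9 (log2 -2.75). The total counts for id1, id4 and 9d9a stayed within 1.5 times under every alternative run, with DESeq2 lowest for id1 (891), id4 (695) and 9d9a (680 against 940), but its windows that rose fell further, from 395 to 248, 290 to 172 and 313 to 197. The 714 slope count (130 up and 348 down) became 1132 with DESeq2, 186 with B73, 714H and 714 alone, and 94 to 971 without 1 leaf library. Most windows called with B73, 714H and 714 alone were not among those edgeR called with all 6 leaf libraries. The same held for most windows called without 714. With fewer libraries the tests have fewer degrees of freedom. The cause of the higher counts was not tested. The low flank correlation of -0.21 ranged from -0.41 to 0.31 without 1 library, and was 0.14 without B73 and 0.31 without 714. In the high flank r stayed between 0.53 and 0.78 over all alternatives. Without 1 library the smallest p possible is 0.05 or 0.2, so those fits could not pass the threshold. With the mean of 4 lines as reference, the flank medians were -0.24 (714) and 0.32 (714H) in the low flank and 0.50 and 0.48 in the high flank, because the 4 reference lines themselves differ there. In 2 Mb scan blocks 28 Mb of B73 root lay below -0.2, against 15 Mb in 5 Mb blocks; the cause was not tested. Of 737 values of named windows under alternatives, 654 kept the threshold, 83 lost it and 0 changed sign. Named windows were chosen as the largest changes, so a change of sign was unlikely in any comparison. The 737 include DESeq2 values at 19 of the 20 leaf and root windows and at 18 of the 20 windows of the 714 slope. Of the 83, 71 lay in the 714 slope, 11 in leaf against root and 1 in 9d9a, all in fits with fewer libraries apart from 1 with the block. Depth limits single windows: the median window has a counting error of 4.4% to 6.6%, and 3 reads make 0.163 CPM in B73 leaf, 0.354 in 9d9a leaf and values between these in the other libraries. The miRNA family, length class and inside or outside gene alternatives were not run, since windows carry no sequences or genes.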

Other observations

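The observations below rest on tests chosen only after the data had been seen.

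In every library the most read window was at 96.1 to 96.2 Mb of chromosome 6. It held 20601 ± 3936 CPM in leaf and 11141 ± 5069 CPM in root (SD, n = 4 lines), higher in leaf in 4 of 4 lines, with a log2 change of 0.90 ± 0.32 (SE) and an adjusted p of 0.0644 in edgeR, which does not pass the threshold. The central part of each chromosome, from 25% to 75% of its length, took 34.9% ± 0.44 of reads in leaf and 34.1% ± 0.42 in root, higher in leaf in 4 of 4 lines by 0.81 points on average, and 4 lines are too few for an exact sign-flip permutation test to reach 0.05. These parts make up 50% of windows.

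B73 was the low line near the end of chromosome 1 and of chromosome 6. At 280 to 285 Mb of chromosome 1 the other 5 leaf libraries lay above B73 by median log2 ratios of 0.33 to 0.39, and the 3 root libraries by 0.21 to 0.28. At 145 to 150 Mb of chromosome 6 the ratios were 0.22 to 0.31 in leaf and 0.17 to 0.26 in root. No explanation was tested for these. B73 was the high line from 30 to 45 Mb of chromosome 1, where the ratios in leaf ran from -1.71 to -0.26, and these blocks are among the lower blocks of id1, id4 and 9d9a weighed below.

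More reads came from 48 to 63 Mb of chromosome 1 in 714 and 714H at windows where id4 and 9d9a were close to B73 in root. In the 29 windows of the high flank in which id4 and 9d9a root lay within 0.3 of B73 root, the median log2 ratio to B73 in leaf was 1.033 in 714 (95% interval 0.70 to 1.30) and 0.496 in 714H (0.30 to 0.72). Both lay above all 10000 random lists. Those lists were not chosen by root level and hold scattered windows, so the rank is no test of the segment. Of these windows 11 lay from 48 to 51 Mb, where id1 was also above B73, and over the 29 the median was 0.13 (-0.11 to 0.95) in id1 over B73 and 0.48 (0.09 to 1.04) in 714 over id1. With other choices of lines and distances it was 0.90 to 1.30 and 0.42 to 0.66, and over the 18 of these windows beyond 51 Mb it was 0.88 (-0.11 to 1.30) and 0.44 (-0.12 to 0.72), intervals that include 0. A greater depth of the B73 leaf library is argued against by the same kind of windows in the low flank, with a median of -0.011 in 714 (-0.30 to 0.15). A sequence difference from the reference shared by 714 and id1 cancels in 714 over id1, whose interquartile range was 0.28 times that of id1 over B73 in the low flank, 0.19 times from 63 to 66 Mb and 0.28 times from 51 to 63 Mb. The interquartile ranges of 714 over id1 themselves were 0.479, 0.26 and 0.588. The median of 714 over id1 was 0.08 and 0.02 in the former regions and 0.881 (0.77 to 0.97) in the latter. With pseudocounts of 0.1 and 5 CPM the latter was 0.984 and 0.669, outside that interval, so its size depends on the pseudocount. The former regions were not refitted in this way. The higher median argues against such a difference as the whole cause from 51 to 63 Mb. From 48 to 51 Mb 714 over id1 was 0.023, which cannot decide on a difference that both lines share. A difference that lowers matching reads would put both lines below B73. The medians over B73 there were 0.99 in id1 leaf (0.83 to 1.11), 0.95 in id1 root (0.76 to 1.06) and 1.04 in 714 leaf (0.82 to 1.23). In each, 24 of 30 windows were higher. These values argue against a difference of that kind as the cause of the rise there. A difference that adds matching reads stays open. Extra copies of the segment in 714 need medians of 1 in 714 and 0.58 in 714H, which the intervals over the 29 windows include. From 48 to 51 Mb id1 lay about as far above B73 as 714 (0.99 and 1.04), so the rise there was not particular to 714. Over all 119 windows from 51 to 63 Mb the median of 714 over B73 was -0.42 (-0.76 to 0.07). Extra copies stay open, as does higher small RNA output per copy.

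Blocks of lower reads in id1, id4 and 9d9a recurred in root, where B73 had no excess depth like that in leaf. Of the 46 blocks of 5 Mb lower in leaf, 100% were also at or below a median log2 of -0.3 in root, which argues against the depth of the B73 leaf library as their cause. Fewer copies of the whole block as the sole cause are argued against in 41 of the 46 by the scatter of windows within them, with an interquartile range over 2 times that of the typical other block of the line. Some of the 41 lay close to this cut, as at 225 and 220 Mb of chromosome 1 in id1 (2.01 and 2.23 times). The argument is weak for those. In the other 5, at 80 Mb of chromosome 1 and 10 Mb of chromosome 2 in id4 and at 5 Mb of chromosome 2 and 90 and 100 Mb of chromosome 7 in 9d9a, the interquartile range was 1.38 to 1.90 times, and fewer copies stay open. Sequence differences between a line and the reference may lower the reads that match. Lines that make less small RNA in these blocks would give the same, so these cannot be told apart without read sequences. At least 64.9% of called windows were lower than B73 in each line, which restates the pattern and favours no cause.

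In blocks where 714 lay below B73 away from 20 to 100 Mb of chromosome 1, mostly on chromosomes 3, 4 and 5, 714H lay below the midpoint of B73 and 714. Over 1546 windows the median log2 ratio of 714H to this midpoint was -0.261 (95% interval -0.29 to -0.24). In a cross of B73 with plants like the sequenced 714, small RNA levels that add up would put it near 0. These libraries departed from that. The interval covers the scatter of neighbouring windows, not of plants, so with 1 library of each such a cross is not excluded. The median ratio to the midpoint ran from -0.45 on chromosome 3 to -0.16 (-0.19 to -0.14) on chromosome 5, where 714H over B73 (-0.40) lay between 0 and 714 over B73 (-0.49). From 33 to 63 Mb of chromosome 1 the median was 0.03 (0.00 to 0.05). The greater depth of the B73 leaf library is argued against by id1, id4 and 9d9a leaf, with depths like that of 714H, whose medians over B73 in the 1546 windows were -0.013 to -0.011. Background haplotypes of both stocks, shared or different, may account for the median log2 ratios to B73 of -0.507 in 714H and -0.49 in 714. A non-additive small RNA level in a true cross, with a median of 714H over 714 of -0.034, would give the same. That median pools blocks that differ. The medians of 714H and 714 over B73 were -0.68 and -0.50 on chromosome 3 and -0.57 and -0.50 on chromosome 4. They were -0.41 and -0.39 on chromosome 1 and -0.40 and -0.49 on chromosome 5. With 1 library of each stock, background haplotypes and a non-additive level cannot be told apart.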
